A study of Homo sapiens with 2 samples.

How the data were processed

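KDM5A occupancy was profiled by chromatin immunoprecipitation and sequencing in T47D cells, an established luminal, oestrogen receptor-positive breast cancer line. There were 2 libraries, 1 per treatment. Cells were kept for 24 h in medium with MK2206, an allosteric inhibitor of AKT kinases, or with its vehicle DMSO. Per the labels' protocols, crosslinked chromatin was sheared by sonication and libraries were made with a commercial kit. The KDM5A antibody came from an academic laboratory.

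The files used were 1 peak list per library, each with the chromosome, start, end, name and score of every peak. Per the submitters' processing notes, FastQC 0.10.0, Bowtie 0.12.7 and MACS2 2.0 were used with the genome build hg19. The notes used here give no role or order for these tools. The control library, the calling threshold and any filtering are not given in the sources used here. The deposited score of each peak has no stated scale, and the files have no header. The lowest scores were 2.21 in the vehicle list and 2.03 in the MK2206 list. The score was therefore used only to rank peaks within a list, and scores from the different lists were not subtracted or divided. Each list carried its own unbroken peak numbering. Whether reads of several libraries of a treatment were pooled before calling is not given in the sources used here. Peak names in the MK2206 list carry the replicate number 2 and those in the vehicle list carry none, and the labels do not say what this number refers to. No peak was narrower than 200 bp in either list.

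Read depth is unknown, because the files give no read counts. With 1 library per treatment, the spread between replicates could not be measured and no p-value was computed. Exact Clopper-Pearson intervals at 95% are given for shares of peaks. They treat peaks as independent, cover counting error over peaks only, and say nothing on variation between cultures. For a share of 0, the upper limit is given as 3 peaks of the total.

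A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Overlap by chance was estimated from 100 random placements of the MK2206 peaks within the stretch between the first and the last peak of each chromosome. Peak density per Mb was taken over the same stretch, since chromosome lengths of the build were not used here. Regions with exactly 1 peak in each list were compared by rank, since both sides of such a comparison have the same length. Starts are printed counting from 1. Overlap counts were checked against bedtools 2.31.1. On simulated lists of 4845 and 6066 peaks with 4000 shared peaks, 4000 were recovered. The simulated sites lay far apart with small shifts, so this checks the counting and not how well close or shifted peaks are matched. The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

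The main set of named peaks followed a rule fixed before the data were examined. It holds the 8 shared regions with the best mean rank, and the 8 highest-scoring peaks of each list that had no counterpart in the other. Other peaks named in the text, such as those picked for their rank difference, lay outside this rule. Regions whose width or score exceeded the 99.9th percentile in both lists were left out of the shared set as potential pile-ups. This removed 6 regions, and whether they are pile-ups was not checked. The overlap rule, the list length, the threshold, merging of close peaks and the set of chromosomes were varied, with the alternatives also fixed in advance except where the text says otherwise.

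The gene table at hand describes another build, GRCh38. It was not used for positions: 100 vehicle peaks and 126 MK2206 peaks lie beyond the last gene of their chromosome in it. Peaks are therefore reported by hg19 position without gene names. The planned comparisons of promoters, of genes with a promoter peak and of 14 gene lists were not made.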

Results

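KDM5A, a histone demethylase that removes methyl groups from lysine 4 of histone H3, was mapped genome-wide in T47D breast cancer cells to compare its binding after AKT inhibition with that under vehicle. The vehicle (DMSO) library gave 4845 peaks covering 2.40 Mb, and the MK2206 library gave 6066 peaks covering 3.11 Mb. The MK2206 list thus held 1.25 times as many peaks and covered 1.29 times the length. Peaks were narrow in both libraries. The median width was 446 bp (interquartile range 292 to 631) with vehicle and 464 bp (304 to 656) with MK2206, and the widest peaks reached 1649 and 1897 bp. Read depth is unknown, and each treatment is represented by 1 library, so none of the differences below could be set against a spread between replicates.

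Most sites occupied by KDM5A with vehicle were also called after MK2206. Of the 4845 vehicle peaks, 4543 overlapped an MK2206 peak, or 93.8% (95% exact interval 93.0 to 94.4). Of the 6066 MK2206 peaks, 4481 overlapped a vehicle peak, or 73.9% (72.7 to 74.97). The remaining peaks were unevenly divided: 1585 were found only with MK2206 and 302 only with vehicle, a ratio of 5.25. Together the lists made up 6322 separate regions. The sequence covered in both amounted to 2.13 Mb, which was 88.5% of the vehicle and 68.4% of the MK2206 coverage. Random placement of the MK2206 peaks gave a median of 12.5 shared vehicle peaks (range 6 to 25 over 100 placements). Moving the MK2206 peaks by 5 kb, a background chosen after seeing the data, left 30 shared vehicle peaks.

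The numbers of unshared peaks depended on where the lists ended and on how overlap was defined. The MK2206-only peaks exceeded the vehicle-only peaks by 1283, and the MK2206 list was longer by 1221 peaks. With the MK2206 list shortened to its 4845 highest-scoring peaks, 719 MK2206 peaks and 639 vehicle peaks lacked a counterpart. With an overlap of at least 50% of both peaks, 838 vehicle peaks and 2059 MK2206 peaks did.

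The strongest KDM5A sites of each library were also called in the other, though not always at a similar rank. Peak scores were ranked within each list and the lists were divided into 10 groups. All of the 1211 peaks in the upper 25% of the vehicle list had an MK2206 counterpart, which allows an unshared share of up to 0.248%. All of the 1518 peaks in the upper 25% of the MK2206 list had a vehicle counterpart, which allows up to 0.198%. In the upper 50%, 2 of 2422 vehicle peaks (0.083%, 0.010 to 0.298) and 49 of 3033 MK2206 peaks (1.62%, 1.20 to 2.13) had no counterpart anywhere in the other list. Compared only with the upper 50% of the other list, 113 vehicle and 733 MK2206 peaks were unmatched. Of the 500 highest-scoring peaks of each list, 403 (80.6%) were among the 500 highest of the other. Sharing fell towards the end of both lists. In the lowest-scoring 10%, 71.3% of vehicle peaks (67.1 to 75.3) and 21.6% of MK2206 peaks (18.4 to 25.1) were shared. Accordingly, the MK2206-only peaks had a median score of 8.27 against 34.0 for the shared MK2206 peaks, and a median width of 275 bp against 548 bp. The vehicle-only peaks had a median score of 6.79 against 22.03 for the shared vehicle peaks, and a median width of 244.5 bp against 466 bp. The lowest-scoring 10% of the MK2206 list lay beyond its first 4845 peaks, the length of the vehicle list. The shares of 71.3% and 21.6% are therefore not for like parts. With both lists at 4845 peaks, the shares over the whole lists were 86.8% and 85.2%.

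**Figure D1:**
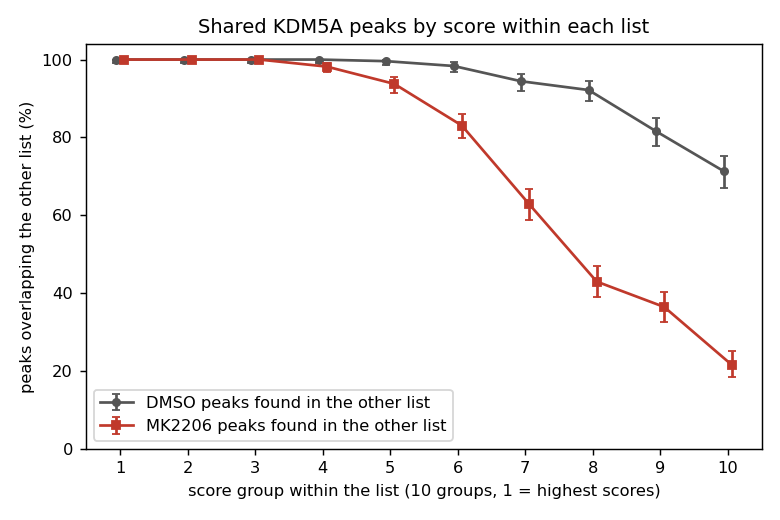
Percent of KDM5A peaks that overlap the other list (vertical axis) in each of 10 score groups of about equal size (horizontal axis, 1 = highest scores), for the DMSO list (circles) and the MK2206 list (squares), with bars for 95% exact intervals over peaks. Both lists start at 100%, and in the lowest group 71.3% of DMSO peaks and 21.6% of MK2206 peaks are shared. The MK2206 list is the longer, so groups of the same number are not like parts of the lists.

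The regions with the best mean rank lay on 6 chromosomes (hg19). The first was a peak at chromosome 1, 206785354 to 206785978, with a score of 309 in the vehicle list. Its MK2206 counterpart, 206785372 to 206785989, had a score of 352. It was followed by a region on chromosome 8 with vehicle limits 146277706 to 146278479 (774 bp) and MK2206 limits 146277696 to 146278430 (735 bp). The third, on chromosome 3, spanned 3220782 to 3221550 with vehicle and 3220955 to 3221571 with MK2206. The fourth, on chromosome 16, spanned 1401443 to 1402461 with vehicle and 1401267 to 1402526 with MK2206. The others of this set had vehicle peaks at chromosome 3, 128879560 to 128880726, chromosome 7, 92861347 to 92862242, chromosome 8, 121457140 to 121458043, and chromosome 17, 26684113 to 26685215. All 8 regions were within the first 0.40% of both lists by score. The highest-scoring peaks of all were among the 6 regions set aside as potential pile-ups, and they are named here after their values were seen. The top vehicle peak lay on chromosome 12 at 124086006 to 124087076, with a score of 374, and the top MK2206 peak on chromosome 12 at 132194953 to 132196341, with a score of 415. The broadest peak of both lists was a region on chromosome 6, 5260570 to 5262218 with vehicle and 5260398 to 5262294 with MK2206.

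Peaks found only after MK2206 were absent from the top of the list. The highest-scoring one was an 829 bp peak on chromosome 15, 91537495 to 91538323, with a score of 43.5, which placed it 30.3% from the top of the MK2206 list. Its nearest vehicle peak was 27.0 kb away. The next, on chromosome 15 at 36871309 to 36871751, had a score of 43.1 and lay 1033 kb from any vehicle peak. Another peak on that chromosome, 48624287 to 48624660, had a score of 42.0 and lay 0.233 kb from a vehicle peak. The others were on chromosome 13 at 73301482 to 73301857 (score 41.5), chromosome 20 at 30467615 to 30468166 (39.7), chromosome 3 at 123304067 to 123304470 (38.7), chromosome 1 at 165599774 to 165600400 (37.1) and chromosome 19 at 9694812 to 9695319 (34.9). These 5 were between 36.2 and 383 kb from the nearest vehicle peak. Among all 1585 MK2206-only peaks, 171 (10.8%, 9.30 to 12.4) lay within 1 kb of a vehicle peak.

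Among the 302 vehicle-only peaks, the highest-scoring one was a 324 bp peak on chromosome 2, 46844266 to 46844589, with a score of 23.2. It was 45.6% from the top of the vehicle list and 559 kb from the nearest MK2206 peak. The next 4 each lay less than 1 kb from an MK2206 peak. They were on chromosome 17 at 7146156 to 7146538 (score 20.7), chromosome 11 at 67979997 to 67980285 (19.3), chromosome 17 at 19265646 to 19265920 (17.6) and chromosome 5 at 36877338 to 36877619 (17.5). The last 3 of the set were on chromosome 6 at 117923421 to 117923687 (16.6), chromosome X at 62780715 to 62780969 (16.5) and chromosome 17 at 74099670 to 74099927 (16.0), and lay 72.8, 1973 and 30.9 kb from the nearest MK2206 peak. In all, 77 of the vehicle-only peaks (25.5%, 20.7 to 30.8) lay within 1 kb of an MK2206 peak.

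At sites occupied in both libraries the order of the peaks was similar and the MK2206 peaks were wider. There were 4284 regions with exactly 1 peak in each list. Across these regions, which are not independent replicates, the Spearman correlation of the scores was 0.88 and that of the widths was 0.78. The centres of the paired peaks lay a median of 38.5 bp apart. The MK2206 peak was the wider in 2901 regions, or 67.7% (66.3 to 69.1), and the widths were equal in 12. The median width was 547 bp with MK2206 and 474 bp with vehicle, and the median ratio was 1.10 (interquartile range 0.96 to 1.32). The rank of a region moved by a median of 7.68 percentage points between the lists, and the 95th percentile of this shift was 29.0 points.

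**Figure D2:**
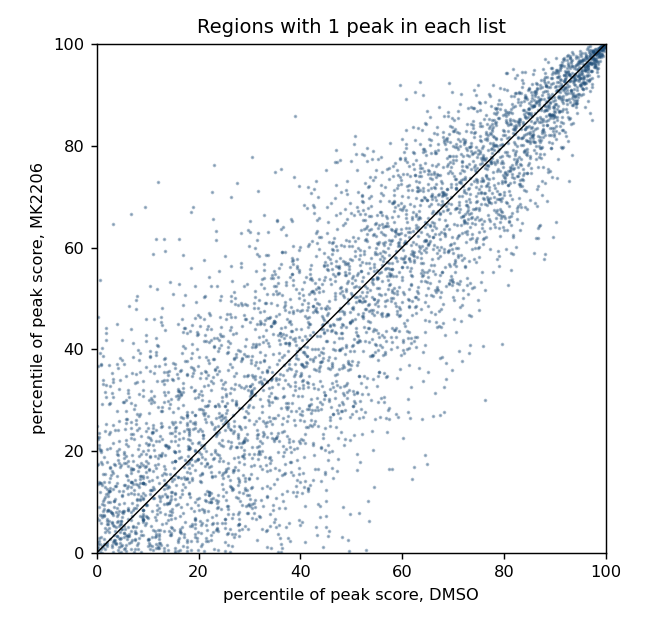
Percentile of the peak score with DMSO (horizontal axis) and with MK2206 (vertical axis), each among the 4284 regions with exactly 1 peak in each list (100 = highest score). Each point is a region and the line marks equal percentiles. Points lie closest to the line at the top, and the Spearman correlation across regions is 0.88.

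The larger number of MK2206 peaks was spread over the genome. Each of chromosomes 1 to 22 and X carried more MK2206 than vehicle peaks, with ratios from 1.17 on chromosome 11 (358 against 305 peaks) to 1.41 on chromosome X (134 against 95). Chromosome 19 was the most densely occupied in both libraries, with 5.77 peaks per Mb with vehicle and 7.27 with MK2206. Chromosome 17 followed with 4.02 and 5.01 peaks per Mb. Chromosomes X and 18 were the sparsest, with 0.63 and 0.66 peaks per Mb with vehicle and 0.89 and 0.84 with MK2206. MK2206-only peaks made up 26.1% of the MK2206 list. The interval of this share excluded 26.1% on 2 of the 23 chromosomes: it was 31.9% on chromosome 6 (26.3 to 38.0) and 20.9% on chromosome 11 (16.9 to 25.5). At the 95% level about 1 in 20 such intervals misses by chance.

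**Figure D3:**
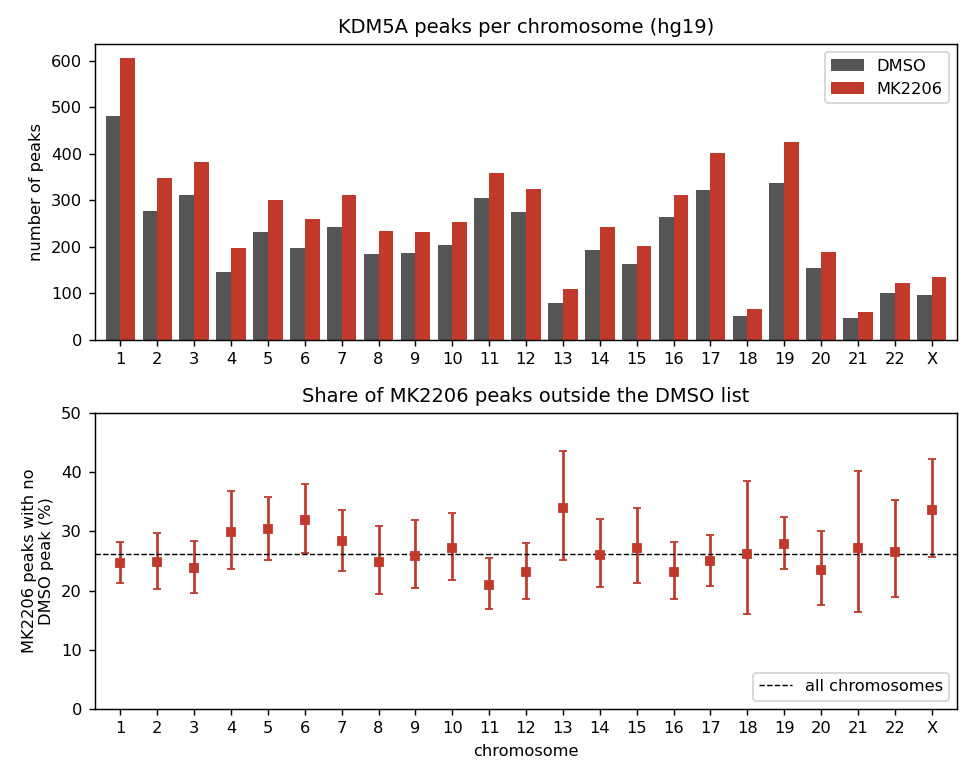
Upper panel, number of KDM5A peaks (vertical axis) on each chromosome (horizontal axis, hg19) with DMSO and MK2206. Lower panel, percent of MK2206 peaks without a DMSO peak on each chromosome, with 95% exact intervals over peaks and a dashed line at 26.1%, the value for all chromosomes. The MK2206 bar is the higher one on all 23 chromosomes shown.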

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

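Depth is unknown and there are no replicates, so what is given here covers only the handling of the peak lists. The excess of MK2206-only over vehicle-only peaks follows largely from list length: it was 1283 peaks, against 1221 more peaks in the MK2206 list, so settings that keep that list longer do not test it. With the upper 50% of each list compared only with the upper 50% of the other, 95.3% of vehicle and 75.8% of MK2206 peaks were shared, leaving 113 and 733 unshared. With lists of equal length the shares were 86.8% and 85.2%, leaving 639 and 719, and equal lengths themselves force the unshared numbers close together. A reciprocal overlap of 50% gave 82.7% and 66.1%, with 838 vehicle-only peaks. Merging peaks within 1 kb gave 94.8% and 76.0%, and counting a peak of the other list within 1 kb as shared gave 95.4% and 76.7%. Moving the MK2206 list by 5 kb, added after seeing the data, left 0.619% of vehicle peaks shared. Of 41 alternative values, the other 25 stayed within the limits of the reported value or within 1.5 times the reported number. They include the median ranks of unshared peaks, which lay between 78.1% and 88.1% from the top under the alternatives. For these medians the limits were the interquartile range of single peaks, 80.1% to 94.9% with vehicle and 70.9% to 92.0% with MK2206. A median could hardly leave so wide a range, so its staying within says little on stability. The lowest and highest chromosome ratios for the upper 50% of the lists were 1.14 on chromosome 2 and 1.47 on chromosome 15, so the extremes fell on other chromosomes than 11 and X. Other promoter windows and thresholds for gene lists were not run, because no annotation of the build was used here. No paired analysis was possible because each treatment had 1 library.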

Other observations

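The test of widths in paired regions and those on distances to neighbouring peaks were set before their results were seen; the tests on the upper 25% of the MK2206 list and on chromosomes were chosen after the scores and peak numbers had been seen.

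Some KDM5A peaks lay in close groups, while the median gap between neighbouring peaks was 156 kb with vehicle and 123 kb with MK2206. In the vehicle list 268 of 4822 gaps between neighbouring peaks were under 1 kb, of which 240 were under 500 bp, while 20 gaps measured 1 to 2 kb and 14 measured 2 to 3 kb. In the MK2206 list 363 of 6042 gaps were under 1 kb, 33 measured 1 to 2 kb and 27 measured 2 to 3 kb. The most densely occupied window of 1 Mb with vehicle was on chromosome 19 from 37 to 38 Mb, with 20 vehicle and 19 MK2206 peaks. Windows on chromosome 11 (62 to 63 Mb), chromosome 16 (2 to 3 Mb), chromosome 3 (49 to 50 Mb) and chromosome 7 (99 to 100 Mb) each held 19 vehicle peaks, with 23, 24, 18 and 21 MK2206 peaks. The window with most MK2206-only peaks was on chromosome 19 from 58 to 59 Mb, where 10 of 25 MK2206 peaks had no vehicle counterpart. On chromosome 4 from 83 to 84 Mb, 7 of 8 did not. These windows were picked for their counts.

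Among the 4284 regions with 1 peak in each list, those whose rank differed most between the lists were picked by that difference. A region on chromosome 11, 17098970 to 17099905, was 96.9% from the top with vehicle and 35.5% with MK2206. Another on chromosome 11, 74303406 to 74304078, was at 88.0% and 27.2%, and one on chromosome 19, 20188662 to 20189195, at 93.3% and 33.5%. In the other direction, a region on chromosome 2, 203102716 to 203103452, was at 47.02% with vehicle and 99.4% with MK2206. A second on chromosome 2, 178417308 to 178417815, was at 50.5% and 99.7%, and one on chromosome 3, 196158620 to 196159345, at 38.1% and 85.6%. Without a second library per treatment, their error is not known. The MK2206 list also held the only peak outside chromosomes 1 to 22 and X, on chromosome Y at 13453492 to 13453696, with a score of 9.02. This peak was 205 bp wide and 79.1% from the top of the list. The reads behind it could not be checked from the peak lists, so it is not evidence of a KDM5A site on chromosome Y.

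The MK2206 list held 1221 more peaks than the vehicle list. No strong site without any vehicle peak was seen. In the upper 25% of the MK2206 list, 0% lacked a vehicle peak (0 of 1518 peaks, which allows up to 0.198%). This cut was chosen after the scores had been seen, and the best-ranked MK2206-only peak lay 30.3% from the top. The zero thus describes the list and does not test for new sites. Sites called weakly with vehicle and strongly with MK2206 do not count as new here. The values argue against split or flanking peaks of vehicle regions as the main part, since 10.8% of the MK2206-only peaks lay within 1 kb of a vehicle peak. Concentration on a few chromosomes was not seen either: all 23 chromosomes carried more MK2206 than vehicle peaks, with ratios from 1.17 to 1.41. The highest upper bound of the MK2206-only share on a chromosome with at least 100 MK2206 peaks was 43.6%. The limit for this bound was chosen after the peak numbers had been seen. With a share of 26.1% over all chromosomes, a chromosome could hold an excess and stay below it, so the bound tests little. Among the explanations left open are a deeper or better enriched MK2206 library and a uniform rise of KDM5A occupancy under AKT inhibition. A difference between the lists in control library, calling threshold or pooling is open too, since none of these is given. The MK2206 peak was the wider in 67.7% of paired regions, which a better library and a uniform rise would both give. That 0% of MK2206-only peaks lay in the upper 25% is the same zero seen from the other side and gives no separate support to any of them. These cannot be told apart, because each treatment has 1 library of unknown depth. A better library and a uniform rise would both lift weak sites over a calling limit, and whether the lists had the same limit is not known.

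The distance of MK2206-only peaks to their neighbours was larger than that of shared peaks at matched score. Without matching, this held after merging close peaks but not for the peaks as deposited. Their median distance to the nearest other MK2206 peak was 52.8 kb, against 42.4 kb (95% of sets 37.5 to 48.3) in 10000 random sets of shared MK2206 peaks matched in 40 score bins, and 100% of these sets had a smaller median. Over all shared peaks, unmatched, the median was 53.4 kb. Another MK2206 peak lay within 1 kb of 17.5% of the MK2206-only peaks (15.6 to 19.4), against 9.66% of all shared peaks (8.81 to 10.6). In score-matched sets, a comparison added after seeing the data, the shared peaks reached 20.4% (95% of sets 18.5 to 22.5). Side fragments of strong regions could shorten the distances of weak shared peaks, but after merging peaks within 1 kb the medians were 74.4 kb and 65.8 kb, and 99.87% of sets were still smaller. Over all shared peaks after merging, unmatched, the median was 63.6 kb. In the lowest-scoring 10% of the MK2206 list 131 of 607 peaks were shared, so the matched sets drew on few shared peaks there. The spread of the sets also leaves out the error of the MK2206-only median itself. The 100% and 99.87% therefore do not measure how sure the difference is. Only the distance to the nearest peak was tested, not the density of whole stretches. Peaks are not replicates, and whether a second pair of libraries would show the same is not known.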
